A study of Mus musculus with 18 samples.

How the data were processed

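Bulk RNA sequencing was measured in 16 libraries and single-cell RNA sequencing in 2 libraries, all from mouse gliomas or cells taken from them. Per the labels, the groups were Ras-driven tumours of mice given vehicle (n = 4) or PLX3397 (n = 4), CD11b-positive cells of PDGFB-driven tumours of mice given PLX3397 (n = 2) or vehicle (n = 1), cell lines grown from Ras tumours (n = 2) and from PDGF tumours (n = 3), and 1 Ras tumour library each by 10x and by Drop-seq. PLX3397 was given daily by mouth at 100 mg/kg, from 7 days after implantation in the Ras tumours and for 3 days from day 14 in the PDGFB tumours. The vehicle libraries of the Ras tumours also carry the treatment label untreated. The bulk tables were deposited as raw counts per gene symbol, with no normalization by the authors. The single-cell tables were deposited as counts of unique molecular identifiers (UMIs) per gene and cell barcode. The processing notes of the authors name FastQC 0.11.7, Trim Galore 0.4.2, cutadapt 1.9.1, STAR 2.6.1e, featureCounts 1.6.2, Cell Ranger and the mouse build GRCm38. The role of each tool, and the version of Cell Ranger, were not given in the sources used here.

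Groups, tests, gene lists, the rule for naming genes and the first set of alternatives were fixed before the data were examined. The line table held 5 further columns that matched no sample, and they were not used. In each table of the tumours and lines, 27 entries whose gene names had turned into dates were left out, at most 0.281% and 0.360% of a library. From the CD11b table, 1 entry without a name was left out. In the Ras tumour and line tables, 62.8% to 69.4% of the counts between 1 and 10 were even numbers, against 39.9% to 41.9% in the CD11b table, a surplus that counting both mates of a read pair separately would give, which was not tested. Library totals were 31.3 to 35.9 M counts (units of 1e6) in the Ras tumours, 26.8 to 30.9 M in the CD11b-positive cells and 32.0 to 35.9 M in the lines.

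Each of the 3 bulk comparisons was fitted alone with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM scaling, the default filter on low counts and robust estimation. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Values per library are counts per M (CPM), given as mean ± SD. Fold changes are log2 values with their standard error (SE). The comparison of CD11b-positive cells has 1 residual degree of freedom, and its lone vehicle library was assumed to vary like the 2 PLX3397 libraries. Fixed gene lists with at least 4 tested members were tested with camera of limma 3.58.1 at an inter-gene correlation of 0.01 on log2 CPM (prior count 2), with fry and with camera at an estimated correlation beside it. A count "adjusted over the list alone" applies the Benjamini-Hochberg correction to the members of 1 list. DESeq2 1.42.0 was run as an alternative. Gene positions are those of GENCODE for GRCm38.

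The named genes were, in each comparison, the 10 called genes with the largest rise and the 10 with the largest fall (mean log2 CPM of at least 3, groups not overlapping, predicted, mitochondrial and ribosomal protein genes left out), up to 4 members per list with the smallest adjusted p, and 12 genes named in advance. Il1r2, Mgl2, Lilra5, Ocstamp, Col14a1, Ptprc and Tyrobp in the Ras tumours, and Itgam, Ptprc, Tyrobp, Col14a1, Il1r2 and Mrc1 in the CD11b-positive cells, were chosen after their values were seen where the rule did not name them.

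Single cells were processed with scanpy in Python. Barcodes were kept with at least 500 UMIs and 300 genes (10x) or 300 UMIs and 200 genes (Drop-seq) and at most 20% mitochondrial UMIs. Scrublet, at its automatic threshold, marked 0 barcodes as doublets in either library, so doublets were not removed. Clusters were made by Leiden at resolution 0.5 on 30 principal components of 2000 variable genes with 15 neighbours. A cluster took the class with most fixed markers at a fold of at least 2, with at least 3 such markers. A further rule was set after the clusters had been seen: a name was kept only if the 10 leading genes of the cluster held at least 1 marker of that class and no more markers of any other class. A stricter form of that rule, without ties, was also tried after the clusters had been seen, and it is given among the alternatives. Shares have exact Clopper-Pearson 95% intervals. Intervals and the limit behind a count of 0 (3 counts) cover counting error only.

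The pipeline was tested on simulated data made from the means, dispersions and library sizes of each comparison, with 200 genes changed. At 4-fold, edgeR found 35 of 67 changed genes among 18366 in the Ras tumour design, 51 of 67 among 15052 in the CD11b design and 0 of 67 among 17475 in the line design. At 8-fold it found 51 of 66, 63 of 66 and 17 of 66. At 2-fold it found 10 of 67, 28 of 67 and 0 of 67. Unchanged genes called by edgeR numbered 6, 34 and 2, and by DESeq2 78, 14 and 127. Camera at 0.01 called a list shifted by 1 on the log2 scale in all 3 designs, and in the CD11b design also 1 list that had not been shifted. Camera with an estimated correlation called the shifted list in the Ras tumour design and missed it in the CD11b and line designs. The simulated genes were drawn independently of each other, so these runs cannot show false list calls that correlated genes would give.

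The first single-cell simulation, with 5 classes of 200 cells each whose markers all had the same level, failed: 0 of 1000 cells got the right name. Without the selection of variable genes 753 of 1000 did. With the selection kept and the depth per cell not limited 510 of 1000 did, so both the selection and the depth bear on the failure. These 510 were 195 of 200 neutrophils, 194 of 200 T cells and 121 of 200 oligodendrocytes. In that run 0 of 200 microglia and 0 of 200 endothelial cells got the right name. A second simulation, written after that failure, drew cells from the profiles of the 10x clusters themselves and so tests only whether the same names come back. There, 822 of 832 cells of the 6 named classes got their name, and 315 of 2488 cells of unnamed clusters got a name that they should not have (1530 of 2488 with the marker count alone).

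Alternatives were another scaling (RLE), DESeq2, no filter on low counts, no robust estimation, an absolute log2 fold of at least 1, leaving out each replicate, replicate number as a block, sample quality weights, and for the cells another resolution, higher minimums and doublets kept. Added after seeing the data were Ddx3y (a gene on the Y chromosome) as a covariate, quality weights for the lines, DESeq2 without each replicate, leaving out the 6% of cells with the highest doublet scores, 5 further seeds and other forms of the naming rule.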

Results

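The series asks how the driver of a glioma bears on its macrophages and microglia and on inhibition of CSF1R, the receptor that these cells need to survive. PLX3397 is a small-molecule inhibitor of CSF1R that also acts on KIT and FLT3. The 18 libraries fall into 8 groups. Ras tumours carried HRasV12 and a dominant negative p53. Depth (M: counts in units of 1e6) was 31.3 to 35.9 M counts per Ras tumour library, 26.8 to 30.9 M per library of CD11b-positive cells and 32.0 to 35.9 M per line. The 10x library held 59.3 M UMIs in 4384 barcodes and the Drop-seq library 9.67 M UMIs in 5000 barcodes.

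The first comparison asks how Ras tumours from mice that received PLX3397 until they were moribund differ from those of vehicle mice. Csf1r itself (chromosome 18, 61100598 to 61132149) stood at 87.1 ± 67.2 CPM under PLX3397 and 250.5 ± 64.4 under vehicle (SD, n = 4 each), a log2 fold of -1.52 (SE 0.57, adjusted p = 0.9998), so this difference did not pass the test. Fcrls, a microglial gene, had a log2 fold of -1.92 (SE 0.45). Of the genes of MHC class II, which presents antigen to T cells, H2-Eb1 (-3.02, SE 0.64), H2-Aa (-2.70, SE 0.60) and Cd74 (-2.56, SE 0.60) had lower values in every PLX3397 library than in every vehicle library, while the libraries overlapped for H2-DMb1 (-2.38) and H2-DMa (-1.70). Ptprc, the pan-leukocyte gene, had a log2 fold of -1.60 (SE 0.42) and Tyrobp, a myeloid adaptor, -1.25 (SE 0.47). Hras (0.10, SE 0.15), Trp53 (0.02, SE 0.23) and the CSF1R ligands Csf1 (-0.01, SE 0.20) and Il34 (0.18, SE 0.16) did not pass the test (adjusted p = 0.9998 each). The counts per gene symbol do not tell HRasV12 or the dominant negative p53 from the endogenous genes. The sign of Csf1 turned with DESeq2 (0.01).

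By the edgeR test 0 of 18366 genes were called, with a smallest adjusted p of 0.0722 for Il1r2, a decoy receptor for interleukin-1 (log2 fold -2.54, SE 0.24). At an unadjusted p under 0.05 there were 648 genes, 572 of them lower. DESeq2 called 169 (3 higher, 166 lower), quality weights 377 (3 higher, 374 lower), and edgeR without the filter on low counts 1. Further genes below every vehicle library, chosen after their values were seen, were Mgl2 (-4.51, SE 0.72), Ocstamp (-3.95, SE 0.56), Lilra5 (-3.57, SE 0.48) and Col14a1 (-2.80, SE 0.36). Mmp9, a matrix protease, had a log2 fold of -3.65 (SE 1.12), with 535.2 CPM in vehicle replicate 4 and 14.5 in vehicle replicate 2, and -2.27 without the former.

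Of 30 lists, camera called 9, of which 6 were lower and 3 higher. All 9 calls were lost with an estimated correlation (smallest adjusted p = 0.773 with an estimated correlation), and without PLX3397 replicate 1 only 4 lists were called, all lower. Over all genes 0 members of any list were called by edgeR. The homeostatic microglia list had a median log2 fold of -0.87 over 14 genes, of which 0 rose and 1 fell adjusted over the list alone; P2ry12 had -1.54 (SE 0.71) and Selplg -1.31 (SE 0.57). The list of monocyte-derived macrophage genes had a median of -0.23 over 15 genes, with 4 that fell adjusted over the list alone: Tgfbi (-1.08), Emilin2 (-1.06), Ms4a7 (-1.89) and Itga4 (-0.85). Antigen presentation had a median of -1.01 over 14 genes, with 7 that fell adjusted over the list alone. Alternative activation had a median of -0.50 over 12 genes (camera adjusted p = 0.0214), with 3 that fell and 1 that rose adjusted over the list alone; Mrc1 had -2.14, Stab1 -0.62, Vsig4 -3.50 and Chil3 1.48. The mesenchymal glioma list had a median of -0.23 over 13 genes (adjusted p = 0.0199). Adjusted over the list alone 1 fell, Tgfbi, which is also counted in the macrophage list. Cebpb had -0.59 and did not pass. The erythroid list had a median of -0.88 over 5 genes (adjusted p = 0.0026), and its haemoglobin genes Hba-a2 and Hbb-bs had -0.88 and -0.93. Whether reads were shared between paralogs of these genes was not tested. With 1 library left out, the microglia, macrophage, antigen presentation and erythroid calls held, but the microglia median moved to -1.86 without PLX3397 replicate 1 and -0.57 without PLX3397 replicate 3, and the erythroid median to -0.52 without PLX3397 replicate 1 (Hbb-bs to -0.55 there and to -1.41 without PLX3397 replicate 4). The macrophage median moved to -0.44 and -0.40 without vehicle replicates 2 and 4 and to -0.52 and -0.71 without PLX3397 replicates 1 and 2. The alternative activation call was lost without vehicle replicate 1 (adjusted p = 0.103) or PLX3397 replicate 1 (adjusted p = 0.140) or 3 (adjusted p = 0.112). The mesenchymal call was lost without vehicle replicate 1 (median -0.13) or 4 (0.0605) or PLX3397 replicate 1 (-0.13).

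The 3 lists called higher were the interferon response (median 0.38 over 15 genes, adjusted p = 0.0224), the oligodendrocyte markers (0.69 over 8, adjusted p = 0.0057) and the astrocyte markers (0.65 over 8, adjusted p = 0.0258), each with 0 members called over all genes or adjusted over the list alone. All 3 calls were lost without vehicle replicate 4, whose scores lay below the other vehicle libraries for astrocytes (3.67 against 6.92 to 7.95) and oligodendrocytes (1.31 against 4.85 to 5.82). Without it the medians were 0.29 for oligodendrocytes (adjusted p = 0.409), 0.29 for astrocytes (adjusted p = 0.477) and 0.30 for the interferon response (adjusted p = 0.133), and without PLX3397 replicate 1 they were 0.0225, 0.13 and 0.30, also not called. Without vehicle replicate 2 the medians were 1.22, 1.01 and 0.21, the last not called. The astrocyte call was also lost without PLX3397 replicate 2 (0.58), and the interferon call without PLX3397 replicates 3 (0.38) and 4 (0.16), while its median was 0.67 without vehicle replicate 1 and 0.60 without PLX3397 replicate 2. Ifit1 had a log2 fold of 0.58 (0.37 without PLX3397 replicate 4) and Ifi44 0.66 (0.42 without it). Ermn had 1.25 and Gfap 0.78, but 0.38 and 0.39 without PLX3397 replicate 1, and 0.83 and 0.38 without vehicle replicate 4. In the interferon list Cxcl9 had -1.91, and -0.78 without vehicle replicate 1. The remaining 21 lists were not called. Among them, 1 member each fell adjusted over the list alone in the disease-associated microglia (Itgax, -2.32), T cell (Cd4, -1.94) and dendritic cell (H2-DMb2, -2.89) lists. The libraries overlapped for Cd3g and Cd8a of the T cell list, and which cells carried Cd4 was not tested. The T cell and NK cell medians were 0.53 and 0.53 while their camera direction was lower, and their scores differed by 1.14 and 1.26 within the libraries with the Y-linked gene Ddx3y but by -0.85 and -1.03 within those without it. The interferon response score differed by -0.04 with Ddx3y and 0.50 without it. Both differences were above 0 for oligodendrocytes (1.03 and 1.40) and astrocytes (0.67 and 1.35). Median and mean also differed in sign for hypoxia and glycolysis (0.03 and -0.03), pericytes (0.03 and -0.01) and oligodendrocyte precursors (0.06 and -0.09). The cell cycle list had a median of -0.11 (adjusted p = 0.0803), and Mki67 had -0.19 (SE 0.32). Leaving out 1 library at a time left 0 genes called by edgeR.

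**Figure D1:**
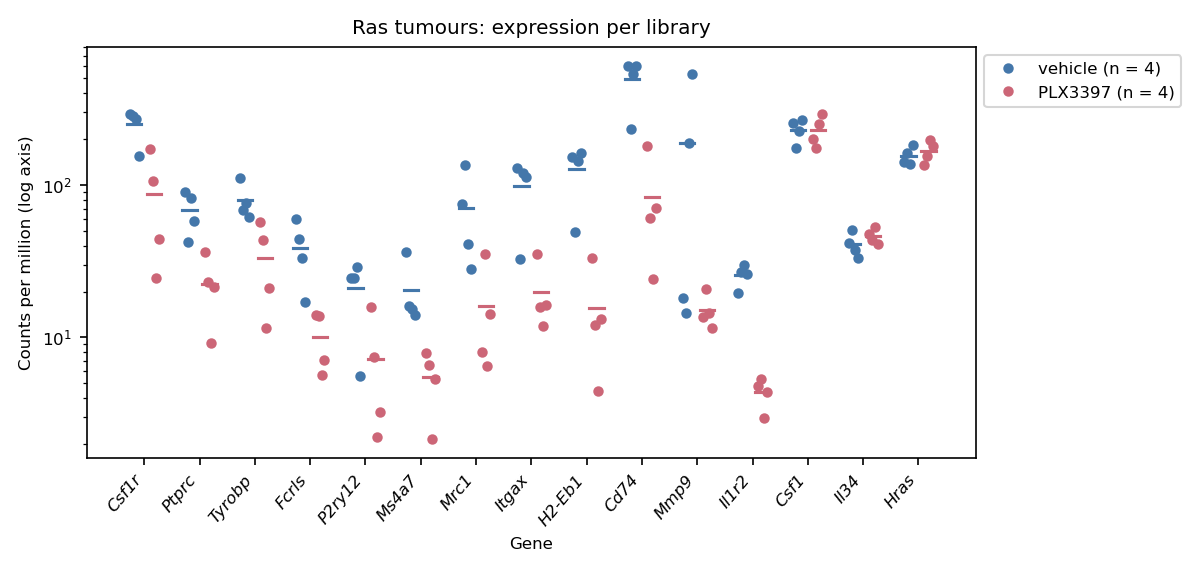
CPM per library (log axis) of 15 genes in Ras tumours under vehicle and PLX3397 (points: libraries, n = 4 each; lines: means). Csf1r means are 250.5 and 87.1 CPM, with overlapping libraries, and Cd74 lies between 24.3 and 179.3 CPM in every PLX3397 library.

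The second comparison asks what 3 days of PLX3397 changed in the CD11b-positive cells of PDGFB tumours. Genes of dividing cells fell: Mki67, a proliferation marker (chromosome 7, 135689784 to 135716361), fell by 2.37 on the log2 scale (SE 0.25), from 448.8 CPM in the vehicle library to 86.6 ± 21.7 CPM (SD, n = 2). Birc5 (-2.10, SE 0.32), Aurkb (-1.94, SE 0.24) and Mcm3 (-1.46, SE 0.17) also fell. Genes of neural and glial cells rose: Slc1a2, an astrocyte glutamate transporter, by 3.12 (SE 0.18), Gfap by 2.95 (SE 0.22) and Pdgfra by 2.48 (SE 0.18). Csf1r was at -0.27 (SE 0.24, adjusted p = 0.504), Itgam, which encodes CD11b, at -0.78 (SE 0.27, adjusted p = 0.141) and Tyrobp at 0.04 (SE 0.21), so none of these passed the test. Ptprc stood at 937.3 CPM in the vehicle library and at 545.6 and 542.1 CPM in the PLX3397 libraries. The ligand Il34 rose by 2.35 (SE 0.33), from 1.87 to 9.55 CPM, while Csf1 was at 0.57 (SE 0.19, adjusted p = 0.131). The rise of Il34 was of the size seen for neural markers below, and which cells carried it was not tested.

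By edgeR 956 of 15052 genes were called, 688 higher and 268 lower, with 4415 at an unadjusted p under 0.05. DESeq2 called 1968 and edgeR without the filter on low counts 1907. The largest rises were A2m (3.87), Nfasc (3.798), Igfbp2 (3.54), Gpr37l1 (3.50), Scg3 (3.45), Prelp (3.37), Ptprz1 (3.35), Olig1 (3.35), Mmp3 (3.28) and Aqp4 (3.25), of which Ptprz1, Olig1 and Aqp4 are known from glial cells. The largest falls were Neil3 (-3.38), Mgl2 (-3.32), Bank1 (-3.04), Ocstamp (-2.75), Rad51ap1 (-2.71), Ch25h (-2.63), Pclaf (-2.57), Tnfsf13b (-2.44), Knl1 (-2.42) and Dok2 (-2.37), of which Neil3, Rad51ap1, Pclaf and Knl1 act in DNA repair, replication or mitosis. With 1 vehicle library, every call rests on that library.

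Camera called 14 of 30 lists, 10 higher and 4 lower, and all were lost with an estimated correlation (smallest adjusted p = 0.775 with an estimated correlation). The comparison has 1 residual degree of freedom, and the estimated correlation came out at 1 for the cell cycle list. In the simulated CD11b design that test missed a list shifted by 1 on the log2 scale. The simulated genes were drawn independently and the shift was smaller than the fall of the cell cycle list, so that miss is a limited guide. With 1 residual degree of freedom behind the estimated correlation, the loss of the calls cannot decide whether they hold. The cell cycle list had a median of -1.68 over 18 genes: 7 fell over all genes and 18 adjusted over the list alone. Antigen presentation had a median of -0.88 over 14 genes (camera adjusted p = 0.0014), with 2 that fell over all genes, H2-DMb1 (-1.65) and H2-DMa (-1.26), and 11 adjusted over the list alone. The interferon response had a median of -0.26 over 14 genes (adjusted p = 0.0161), with 1 that fell in both counts, Cxcl9 (-1.84). The homeostatic microglia list had a median of -0.34 over 14 genes (adjusted p = 0.0363), with 1 that fell in both counts, Siglech (-0.98); Cx3cr1 had -0.90 and P2ry12 -0.84.

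Of the lists called higher, 4 hold markers of neural cells: astrocyte (median 2.16, 6 of 8 rose over all genes and 8 adjusted over the list alone), oligodendrocyte precursor (2.67, 3 of 8 and 8), oligodendrocyte (1.98, 3 of 8 and 5) and neuron (2.12, 4 of 8 and 4). Mobp rose by 3.09, Mbp by 1.39, Nefl by 2.35 and Camk2a by 1.63. The proneural glioma list had a median of 2.33 over 9 genes, with 4 that rose over all genes and 8 adjusted over the list alone; Sox2 rose by 2.39 and Olig2 by 2.96. The other 5 lists called higher were endothelial (median 1.45, 0 of 10 rose over all genes and 8 adjusted over the list alone), pericyte (1.21, 1 of 8 and 2), fibroblast (2.21, 1 of 7 and 5), extracellular matrix (2.15, 5 of 14 and 11) and angiogenic factors (1.38, 0 of 12 and 0). Each of these 10 calls was lost with an estimated correlation (adjusted p = 0.775), a test that cannot decide in this design, as said above. Col6a1 rose by 2.53, Postn by 2.21, Pdgfrb by 2.09 and Col3a1 by 2.46, and Cldn5 had 1.45. By contrast the medians of lymphocyte markers lay near 0, at -0.17 for T cells and 0.01 for NK cells, and for NK cells camera and the mean (-0.18) had the other sign.

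Of single genes in lists that were not called, Ccl7 (-1.32), Ccl12 (-1.31) and Ccl2 (-0.998), which attract monocytes, fell, while Cx3cl1 (2.12) and Ccl22 (1.83) rose and Ccl5 had 1.37. Of the feedback genes of the MAPK pathway, Spry2 (2.05), Spry4 (2.15) and Etv4 (1.504) rose and Etv5 (-0.97) fell. Cx3cl1, Spry2 and Spry4 rose about as much as the neuron markers (median 2.12), and which cells carried them was not tested. Fabp5, a disease-associated microglia gene, rose by 1.88, while Gpnmb had 1.84 and Igf1 1.35.

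**Figure D2:**
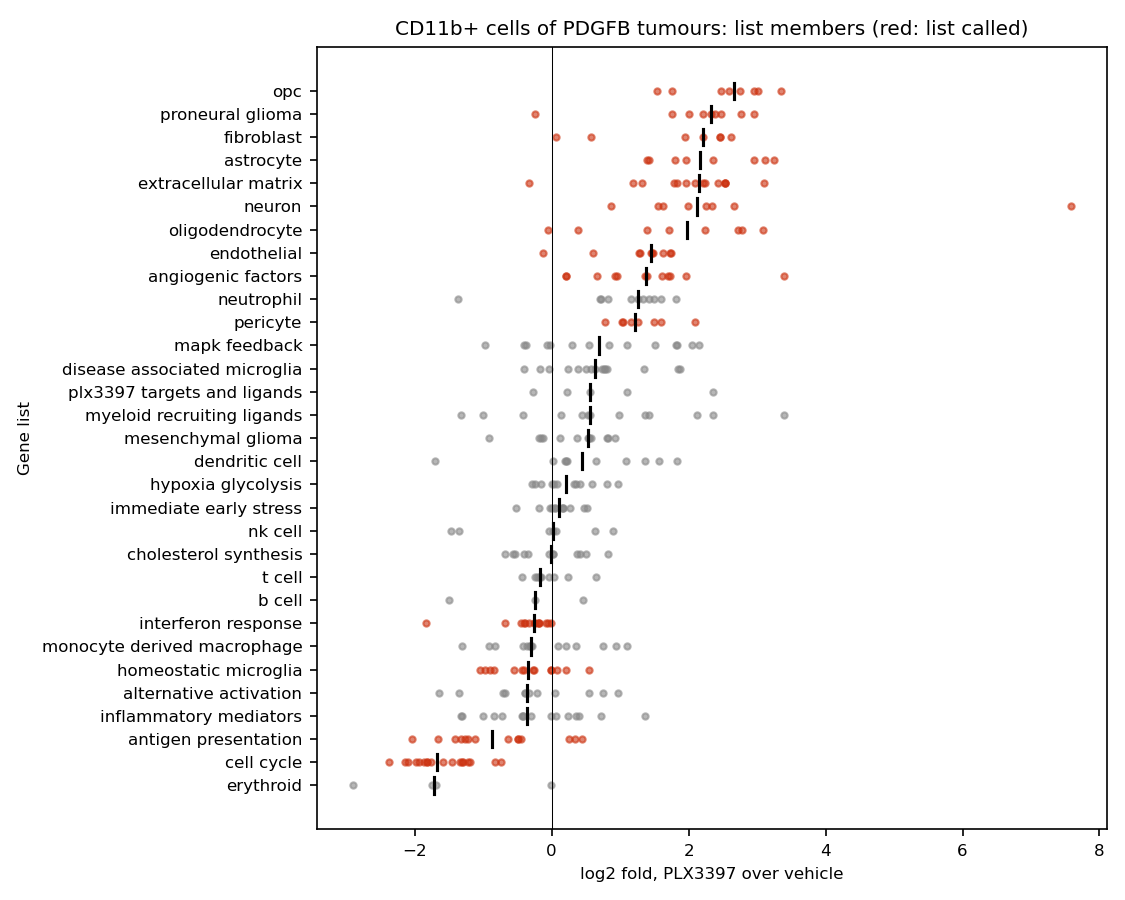
Log2 fold (PLX3397 over vehicle, n = 2 and n = 1) of each member of the gene lists in CD11b-positive cells of PDGFB tumours (points: genes; black bars: list medians; red: lists called by camera at a correlation of 0.01). The cell cycle median is -1.68 and the oligodendrocyte precursor median 2.67.

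The third comparison asks how lines from Ras tumours differ from lines from PDGF tumours; the media also differed, as those of the PDGF lines held PDGF proteins and those of the Ras lines did not. Sox10, a transcription factor of the oligodendrocyte lineage (chromosome 15, 79154908 to 79165240), stood at 0.76 ± 0.33 CPM in the Ras lines (SD, n = 2) and 860.9 ± 234.6 in the PDGF lines (n = 3), a log2 fold of -10.14 (SE 0.59, adjusted p = 0.120). Pdgfb, the driver of the latter, stood at 1.54 ± 2.05 against 171.2 ± 48.2 CPM (-6.79, SE 1.53), and Hras at 118.7 ± 65.3 against 50.8 ± 3.52 CPM (1.22, SE 0.37). Cspg4 (-3.10, SE 0.37) and Bcan (-1.89, SE 0.35), both of precursor cells, were lower in both Ras lines. Csf1 had a log2 fold of 2.00 (SE 0.72) and Il34 3.39 (SE 1.13), both with a large spread between the Ras lines. Csf1 stood at 148.3 CPM in Ras line 1 and 31.4 in Ras line 2, the latter below the 31.6 of PDGF line 3, and Il34 at 29.5 and 2.89 CPM. Without Ras line 1 the log2 folds were 0.48 for Csf1, 0.91 for Il34 and -10.80 for Pdgfb, and without Ras line 2 that of Hras was 0.49.

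By edgeR 0 of 17475 genes were called, with 2842 at an unadjusted p under 0.05 (1538 higher, 1304 lower), while DESeq2 called 2110 (1041 higher, 1069 lower) and edgeR without the filter on low counts 1. Without Ras line 2, edgeR called 2111, with the lone Ras line assumed to vary like the PDGF lines. Spread was large between the 2 Ras lines: Spp1 stood at 3067 and 109.8 CPM and Fn1 at 3904 and 70.4.

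Camera called 8 of 26 lists, 5 higher and 3 lower, and all were lost with an estimated correlation (smallest adjusted p = 0.276 with an estimated correlation); without PDGF line 2 it called 5. Fry called 3 of them, the proneural, oligodendrocyte precursor and oligodendrocyte lists, all lower. Over all genes 0 members of any list were called. The precursor list had a median of -3.59 over 8 genes, with 5 that fell adjusted over the list alone; C1ql1 had -4.08 and Gpr17 -5.06. The oligodendrocyte list had -3.49 over 7, with 4 that fell adjusted over the list alone, and Mag had -6.36 and Mbp -4.73. The proneural list had -1.02 over 12, with 2 that fell adjusted over the list alone. Of the lists called higher, the interferon response had a median of 2.68 over 13 genes, with 4 that rose adjusted over the list alone; Oasl2 had 5.49 and Ifi44 5.80. The mesenchymal list had 2.10 over 13, with 4 that rose adjusted over the list alone; Cd44 had 3.91 and Plaur 5.41. Extracellular matrix had 3.36 over 14 (0 adjusted over the list alone), ligands that recruit myeloid cells 2.00 over 11 (0) and inflammatory mediators 1.48 over 6 (1), with Fn1 at 6.17, Ccl5 at 2.43 and Ptgs2 at 3.53. PDGF line 3 stood apart from PDGF lines 1 and 2 in the inflammatory score (0.53 against -1.99 and -2.36). It also held counts of myeloid genes that were at most 10 in any other line: 162 of Csf1r and, chosen after their values were seen, 507 of Tyrobp, 74 of Itgam and 65 of Ptprc; their source was not tested. Antigen presentation had a median of 0.85 while its camera direction was lower, and median and mean differed in sign for fibroblasts (0.86 and -1.13) and astrocytes (-0.03 and 0.43); the endothelial median was -0.29 with a camera direction of higher. Kit, Mki67 and Vegfa had log2 folds of 0.14, -0.10 and 0.19, and the sign of Vegfa turned with quality weights (-0.55). Without Ras line 1 the medians moved to 0.68 for extracellular matrix and 0.48 for recruiting ligands, both no longer called, and to 1.44 for interferon, 0.58 for mesenchymal, -0.53 for proneural and -2.18 for oligodendrocyte genes. Single genes moved too without Ras line 1: Fn1 to 1.35, Oasl2 to 3.64, Cd44 to 2.58, Plaur to 3.198 and Mag to -9.55, and Gpr17 to -8.35 without Ras line 2. Without Ras line 2 they were 0.83 for inflammatory mediators, no longer called, and -2.66 for proneural genes. Without PDGF line 2 the matrix (3.14), recruiting (1.76) and inflammatory (1.22) calls were lost, and inflammatory mediators were not called without PDGF line 1 (adjusted p = 0.0751) and stood at 3.89 without PDGF line 3.

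**Figure D3:**
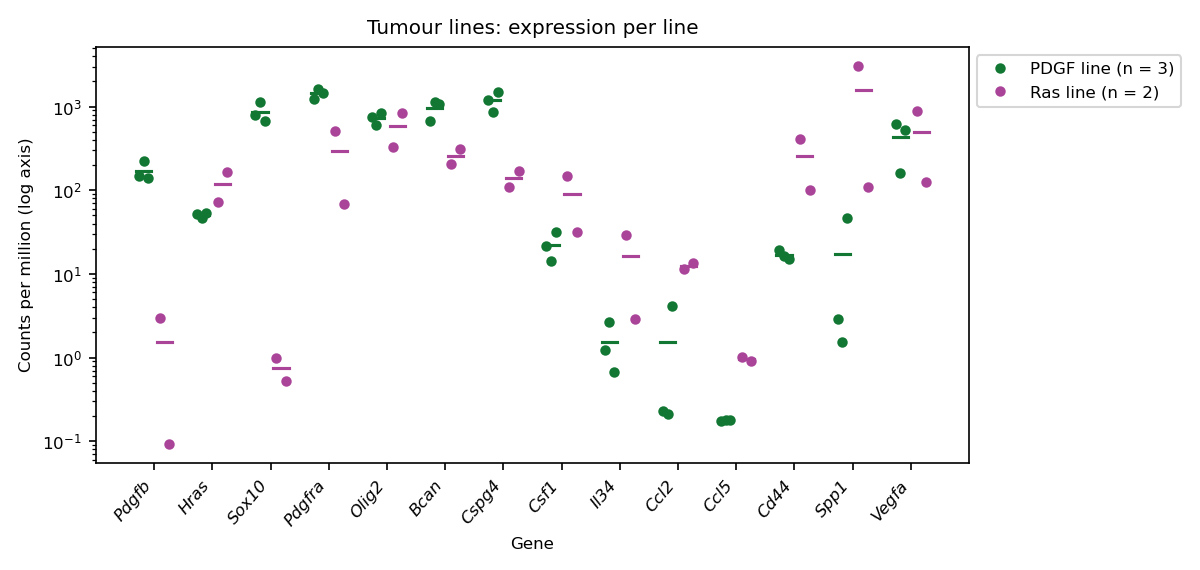
CPM per line (log axis) of 14 genes in Ras lines and PDGF lines (points: lines, n = 2 and n = 3; lines: means). Sox10 means are 0.76 CPM in the Ras lines and 860.9 CPM in the PDGF lines.

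The single-cell libraries show which cells an untreated Ras tumour holds, with 1 library per platform and no replicates. In the 10x library 3320 cells were kept (median 8351 UMIs and 2653 genes). Microglia-like cells made up 8.37% (278 cells, 95% interval 7.45 to 9.37) and monocyte or macrophage-like cells 7.83% (260 cells, 6.94 to 8.80), together 16.2% (14.97 to 17.5). Neutrophil-like cells made up 2.44% (81 cells), erythroid-like cells 5.12% (170), B cell-like cells 0.783% (26) and T cell-like cells 0.512% (17), the last of which also showed the NK genes Gzma and Klre1 among their leading genes. The remaining 74.9% lay in clusters without a name, among them 952 cells in clusters that the marker count alone would have named. The simulated cells from these profiles were named in 315 of 2488 cases where they should not have been, and in 1530 with the marker count alone, so small classes are read with that limit. In the simulation with equal marker levels and the selection of variable genes kept, 0 of 200 microglia got their name, with the depth limited or not. Keeping at most 10% mitochondrial UMIs gave a share of 17.7% for microglia plus monocytes and macrophages, and a doubled minimum of UMIs gave 18.1%. At resolution 1.0 it was 16.5%, but 11.7% there when names resting on a tie were left out.

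Csf1r was found in 92.3% of the monocyte or macrophage-like cells (531.8 CPM) and 57.9% of the microglia-like cells (392.8 CPM), against 1.18% of erythroid-like cells, with median depths of 15502.5, 2574 and 2326.5 UMIs. Ccr2, a receptor of recruited monocytes, stood at 158.9 CPM in the monocyte or macrophage-like cells and 9.87 in the microglia-like cells. Arg1 stood at 2683 and 1328 CPM and Spp1 at 10565 and 7707 CPM. Il1b was highest in the neutrophil-like cells, at 7556 CPM and in 82.7% of cells, against 843.8 CPM in the monocyte or macrophage-like cells. Leading genes were Fcrls and Trem2 for the microglia-like cells, Rgs1, Ccr2 and Thbs1 for the monocyte or macrophage-like cells and S100a8 and S100a9 for the neutrophil-like cells. The monocyte or macrophage-like cells held 12 of their fixed markers at a fold of at least 2 against 9 of the next class. The microglia-like cells held 9 of theirs against 8 of the next class. P2ry12 was found in 10.4% and Siglech in 6.83% of the microglia-like cells, and Sall1 stood at 0.721 times its level in other cells. P2ry12 stood at 30.3 CPM in them and 6.08 in all other cells, and Cx3cr1 at 228.5 and 45.9. These genes were thus not confined to that class, and the division between the 2 classes is read with that limit.

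In the Drop-seq library 4901 cells were kept (median 1396 UMIs and 906 genes). Monocyte or macrophage-like cells made up 3.69% (181 cells, 3.18 to 4.26), led by C1qa, Lyz2 and Cd74 and with no microglia class beside them. They held 12 of their fixed markers at a fold of at least 2 against 9 of the next class. Oligodendrocyte-like cells made up 0.449% (22 cells), led by Klk6 and Mag. A cluster of 742 cells (15.1%, 14.1 to 16.2) was called astrocyte-like on a tie, since its leading genes held 1 astrocyte marker and 1 glioma marker. Of the astrocyte markers, Aqp4 and Aldh1l1 were each found in 0.674% of these cells, Agt in 0.270% and Gja1 at 0.533 times its level in other cells, while S100b was found in 47.2%, so the name is weakly supported. Csf1r was found in 38.1% of the monocyte or macrophage-like cells and 0.674% of the astrocyte-like cells, with median depths of 1082 and 1127 UMIs. The 2 platforms differ in animals and in depth, and no test was made between them.

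**Figure D4:**
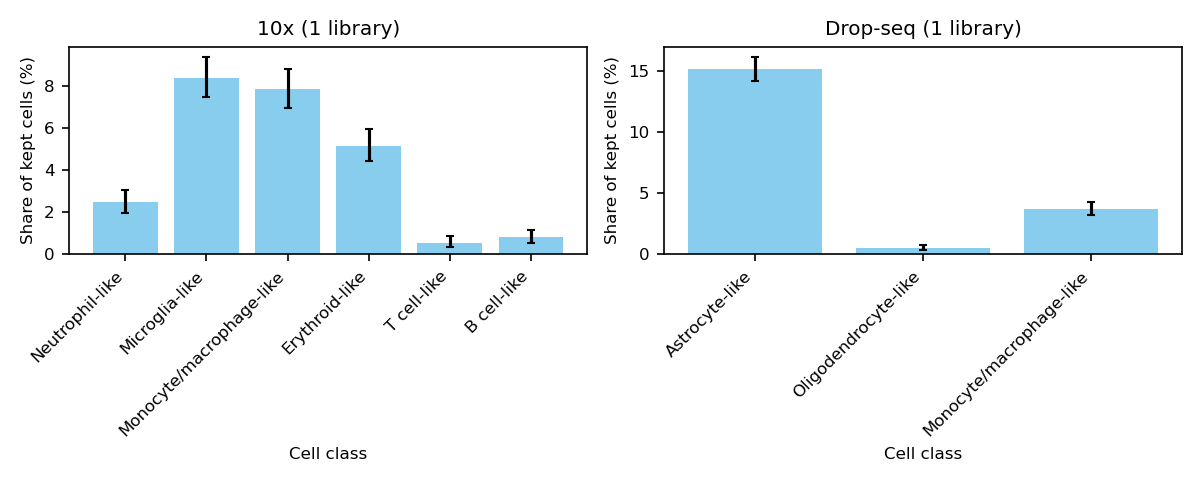
Share of kept cells (%) in each named class of the 10x and Drop-seq libraries of Ras tumours (bars: share; error bars: exact 95% intervals; 1 library each). Microglia-like plus monocyte or macrophage-like cells are 16.2% in the 10x library and 3.69% in the Drop-seq library, which has no separate microglia class.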

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

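The tests of a lower myeloid share, of vehicle replicate 4 and of Ddx3y were chosen only after the result was seen; the tests of carry-over and of other splits were written before. Dixon's criterion picks out about 1 group in 20 by chance, and here it picked out 20 of 170 groups of 4 Ras tumour libraries.

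In the Ras tumours vehicle replicate 4 stood apart from the other vehicle libraries (gap divided by range) in the scores of the homeostatic microglia (0.843), MAPK feedback (0.993), pericyte (0.897) and oligodendrocyte precursor (0.843) lists. It also stood apart in Csf1r (0.874), P2ry12 (0.899), Selplg (0.872), Emilin2 (0.879), Cd4 (0.927) and Gfap (0.866). Vehicle replicate 2 stood apart in Il1b (0.843), Itgax (0.900), H2-Eb1 (0.896), H2-Aa (0.925), H2-Ab1 (0.887), Cd74 (0.863) and H2-DMb2 (0.908). Vehicle replicate 1 stood apart in Ms4a7 (0.848) and Hba-a2 (0.880), and PLX3397 replicate 1 in the proneural glioma score (0.876).

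The first pattern weighed is the lower myeloid genes in Ras tumours under PLX3397. Leaving out vehicle replicate 4 tests nothing here: its score in the homeostatic microglia list was 3.69 against 5.03 to 5.29 in the other vehicle libraries, so the median could only deepen, to -1.27. Ddx3y was expressed by 2 libraries of each group, so a shift tied to it alone would cancel between the groups. The log2 fold of Csf1r was -1.09 within the libraries with Ddx3y and -2.63 within those without (smaller drop -1.09). With this balance, and with 1 gene already seen to be lower, this check adds no evidence. Whether Ddx3y came from the host or the implanted cells was not tested, and Xist stood at 239 to 724 CPM in all 8 libraries. The real 0 genes called by edgeR (highest other 3) cannot be tested by splits, as all 35 reach it, but chance could not be excluded for the rest: of the 35 splits, 22 gave as many lists as the real 9 (highest other 16), 12 as many genes at an unadjusted p under 0.05 as the real 648 (highest other 6073) and 6 as many DESeq2 calls as the real 169 (highest other 4004). The split with 6073 and 4004 calls set vehicle replicates 1 and 4 with PLX3397 replicates 3 and 4 against the rest. It follows the sign of the first principal component (64.5% of the variance) and points to a structure apart from treatment, as does the split by Ddx3y (1486 by DESeq2). Neuron scores were 7.07 to 8.52 in the libraries above 0 on that component and 3.37 to 6.98 in those below. Astrocyte scores were 7.52 to 8.43 and 3.67 to 7.24. The component thus goes with the level of neural markers, and the cause was not tested. An effect of PLX3397 stays open.

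The second pattern is the higher glial and stromal genes in CD11b-positive cells under PLX3397. A lower myeloid share that raises every other cell type alike could not be judged from lymphocyte markers. The median of 20 such markers was -0.10 (SD over genes 0.65) and that of 32 neural markers 2.30 (SD 1.27), a difference of -2.40. This test was chosen after the result was seen, and several lymphocyte markers lay near the floor. In the vehicle library Ms4a1 stood at 0.40 CPM, Cd79a at 0.50 and Prf1 at 1.17. Of the T cell markers, Cd8a stood at 2.94, Lck at 4.84, Ctla4 at 15.4 and Cd4 at 49.6, and which cells carried Cd4 was not tested. A lower myeloid share therefore stays open. Carry-over of tumour and brain cells with the beads would raise the 50 most abundant genes of non-immune 10x cells. Of these, 47 were above 0 with a median of 1.85, and 19 were called higher and 1 lower. However, Olig1, Ptprz1, Igfbp2 and Pdgfra are among the 50 and had already been named above as rising. A lower myeloid share or uptake of RNA would raise such genes too, so this test does not single out carry-over. The 10x profile comes from a Ras tumour and stands in for PDGFB tumours. RNA taken up by myeloid cells from dying neighbours, and a change within the myeloid cells, were not tested and stay open, as does any difference of the single vehicle library.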

How the results depend on the processing

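DESeq2 without each replicate, Ddx3y as a covariate, quality weights for the lines, the doublet scores, seeds and naming rules were added after the data were seen; the cause of each change below was not tested unless stated. In the Ras tumours genes called moved from 0 to 169 with DESeq2, 377 with quality weights and 1 without a filter, and stayed 0 with RLE scaling, a replicate block, Ddx3y and each library left out (0 to 0). Lists called moved from 9 to 0 with an estimated correlation and 0 with directional fry, and ranged from 4 (without PLX3397 replicate 1) to 12 with 1 library left out. In the CD11b-positive cells genes called moved from 956 to 1968 with DESeq2 and 1907 without a filter, and lists called from 14 to 0 with an estimated correlation and 0 with fry; leaving out a PLX3397 library gave log2 folds with no test. Of the 956 genes, 953 were among those of DESeq2. In the lines genes called moved from 0 to 2110 with DESeq2 and 1 without a filter and ranged from 0 to 2111 (without Ras line 2) with 1 line left out, while lists called moved from 8 to 0 with an estimated correlation and 3 with fry, and ranged from 5 (without PDGF line 2) to 9. The simulated designs gave 127 false calls by DESeq2 in the lines and 78 in the Ras tumours, against 2 and 6 by edgeR, and in the CD11b design 14 by DESeq2 against 34 by edgeR.

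Replicate numbers did not steadily pair the Ras tumour libraries: correlations of the same number were 0.114, 0.132, -0.420 and 0.450. In the lines they were -0.177 and -0.107. The deviations of the 2 Ras lines from their mean mirror each other, so these values cannot show pairing or its absence. With a replicate block, lists called were 11 in the Ras tumours and 10 in the lines, Trp53 turned to -0.00841 in the Ras tumours and Mki67 to 0.10 in the lines.

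Alternatives were run for the named genes. In the Ras tumours Csf1 turned to 0.0123 with RLE scaling, 0.0123 with DESeq2 and 0.24 with quality weights, Trp53 to -0.00466 with Ddx3y, and with quality weights Kit to -0.48, Pdgfb to 0.0585, Mki67 to 0.0770 and Vegfa to 0.44. With 1 library left out, Csf1 ranged from -0.14 to 0.10, Kit from -0.18 to 0.46, Mki67 from -0.42 to 0.0356, Pdgfb from -0.71 to 0.0639, Trp53 from -0.11 to 0.19 and Vegfa from -0.49 to 0.26. In the lines Vegfa turned to -0.55 with quality weights, and with 1 line left out Kit ranged from -0.34 to 0.48, Mki67 from -0.61 to 0.27 and Vegfa from -1.79 to 0.97.

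The 10x share of 16.2% moved to 18.1% with the minimum UMIs doubled, 17.7% with at most 10% mitochondrial UMIs and 11.7% at resolution 1.0 with names on a tie left out. It was 16.2% with names from the marker count alone, the rule fixed before the data were examined, and 15.5% to 16.5% otherwise. The Drop-seq share of 3.69% stayed between 3.42% and 3.95%.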

Other observations

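The tests of the cluster with Alb were chosen only after the result was seen; those of the 10x classes and of the genes shared between treatments were written before.

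A cluster of 38 cells of the 10x library (median 679 UMIs) was led by Alb, Ttr, Tm4sf4, Krt8 and Krt18. Alb had 136 UMIs there and 3 in all other cells. For choroid plexus epithelium, 0 of 12 markers had a UMI in at least 25% of these cells. Most hepatocyte markers missed that limit too at this depth, and Ttr was not among the 12, so choroid plexus was not excluded. Hepatocytes cannot be told apart from another source: 2 of 12 hepatocyte markers, Alb (89.5% of cells) and Ambp (65.8%), passed that limit, yet 12 of 12 had a UMI in the cluster (3 of 12 for choroid plexus), 8 of them in only 5.26% or 7.89% of its 38 cells, with folds over other cells from 100.9 (Fgb) to 4375 (Alb) except Trf (0.809), and the low depth keeps it open. The limit of 25% was chosen after the values were seen, and the source of these cells was not tested further.

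One hypothesis was that the genes lower in Ras tumours under PLX3397 are those of myeloid cells. Of 462 genes lower at an unadjusted p under 0.05 with a 10x level, 164 (35.5%) were highest in a myeloid class, against 4.66% of 12736 tested genes. By class, 34.4% of the lower genes were highest in monocyte or macrophage-like and 1.08% in microglia-like cells. The shares of all tested genes in each of these classes were not computed, so this division does not favour either class. Neutrophil-like cells were not counted as a myeloid class here, and a further 26.2% of the lower genes were highest in them, against 8.99% of all tested genes. This is consistent with a lower myeloid share or lower expression within it, which these data do not separate, and chance was not excluded for the comparison itself.

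A second hypothesis was that genes that fell in CD11b-positive cells are also lower than other myeloid genes in Ras tumours. Leaving out 6 genes noticed beforehand, 82 such genes had a median log2 fold of -1.43 there, against -0.47 for the rest of 947 myeloid genes, and 75 of 82 were below 0, against 86.0% of the other myeloid genes. The test did not pass with an estimated correlation (p = 0.315 by camera, correlation 0.46), though it did at 0.01 (p = 9.18e-07), so this hypothesis stays open. Of 13929 genes tested in both comparisons, 77 were in both lower sets, where 9.02 would be there by chance if genes were independent, which they are not. That chance value also draws from all genes, while CD11b-positive cells are myeloid and myeloid genes were frequent among the lower genes of the Ras tumours. An overlap above it was therefore to be awaited from shared cell type alone. The 77 include Mgl2, Ocstamp, Col14a1 and Abcg3, which had been left out of the test above.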
